A study of Eisenia fetida with 4 samples.

How the data were processed

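The data are scanner readings of 2 Agilent 244K arrays hybridised with 1 pool of *Eisenia fetida* total RNA. Per the labels, 0.5 ug of RNA was amplified and labelled with Cy3 in a one-colour protocol, and the design holds probes of 60 or 40 bases. Per the file headers, the slides were read on a GenePix scanner at 532 nm with 5 um pixels and at PMT gains of 400 and 500, and spots were quantified with GenePix Pro 6.1 using the local background of each feature and no normalisation. The deposited intensity values are, per the file headers, the median and mean pixel brightness of each spot, the median and SD of its local background, and the spot median minus the background median. The percent of saturated pixels of each spot was also given by the scanner software, per the file headers. The signal-to-noise score in the deposited files comes from the same software, per the file headers. The authors' series value table holds intensity too, and matched the background-subtracted medians in 100% of spots, which settles its scale, centring and direction: linear, uncentred, brighter spots higher. Its medians were 19 and 19 at gain 400 and 92 and 91 at gain 500, for array 1 and array 2. Any further step by the authors is not given in the sources used here.

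Scans were grouped by the PMT gain in their labels, with the array number as the replicate number. A probe was called detected when its foreground median exceeded its local background median by more than 2 background SDs. No spot carried a bad or not-found mark. A probe was called saturated when over 50% of its pixels were saturated or its median stood at the top of the scale. Control spots were left out of all counts of earthworm probes. The detected share, the saturated count and the ratio of gain 500 over gain 400 were computed per scan or array and given as mean ± SD over 2 arrays. Differences between gains in the first 2 were taken within each array and tested over all sign changes, a test chosen after the data were seen. The number of arrays, not the number of probes, limits the precision. Agreement between arrays was computed as the log2 ratio of background-subtracted medians over probes detected on both, and the gain ratio over probes detected and unsaturated on both scans of an array. These statistics were tested on simulated data first.

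For the test between gains, intensities were background-corrected by normexp with an offset of 50, quantile normalised over the 4 scans, and fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Same-numbered scans are rescans of the same hybridised slide per the labels, so the array number pairs them. After normalisation the deviations of same-numbered scans from their gain means correlated at only 0.0377. That value covers all earthworm probes, 66.9% of them detected on no scan, so it does not show that brighter probes lack a shared slide effect. A fit with the array number as a block gave 0 calls, with 1 residual degree of freedom left. The simulated test of limma held 50 probes at each of 4 sizes of change and made 0 false calls. Its 2 larger sizes and its brightness-dependent noise were adopted after earlier versions had recovered no probe changed by 1 or 2 on the log2 scale.

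The design, the comparisons, the alternatives and the rule for naming probes were fixed before the data were examined, apart from the tests and alternatives named as later choices. The rule named the 10 brightest unsaturated probes at gain 400, the probes with the largest change between gains past the threshold (there were none), the 5 with the largest ratio between arrays of the same sign at both gains, and every control class. At most 2 identifiers per direction are printed because the files give no gene name, description or sequence match for any earthworm probe. For that reason 3 of 9 planned results were not run: detection by probe length, agreement among probes of one target, and the lists of genes with the cell type markers. Alternatives covered the detection rule, background correction, foreground mean, filters, normalisation, saturation rule, value table and leaving out each array or scan. Correlations across slide sectors and spots used two-sided permutation tests with 100000 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with the R package data.table (version 1.17.8) for reading files.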

Results

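Total RNA pooled from adults, juveniles and cocoons of the earthworm *Eisenia fetida* was hybridised to 2 arrays of one Agilent 244K design that carries candidate earthworm probes of 60 or 40 bases. Each array was read at photomultiplier (PMT) gains of 400 and 500, the PMT being the scanner's light amplifier, which gave 4 scans in 2 groups of 2. According to the labels, the arrays served to test the probes, so the design implies comparisons between slides and between scanner settings, and none between biological conditions. All 4 scans come from 1 RNA pool, and every SD or p-value here therefore measures technical spread. Each scan held 243504 spots: 241399 earthworm probes with 1 spot each, and 2105 control spots of 60 control sequences. The files pair the earthworm probes with no gene name, so probes are given by their identifiers.

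The first comparison asked how many candidate probes exceeded their local background by more than 2 background SDs. Most did not. At gain 400 the detected share was 25.6% ± 0.230 (SD, n = 2 arrays), with 61299 probes on array 1 and 62084 on array 2. At gain 500 it was 25.1% ± 0.784 (SD, n = 2 arrays), with 59196 and 61873 probes. Of the 602 negative control spots, 2 on array 1 and 3 on array 2 passed the same rule at gain 400, and 2 and 0 at gain 500. On all 4 scans together 47702 probes (19.8%) were detected, 161553 (66.9%) were detected on no scan, and 32144 were detected on some scans only. Both slides read lower at gain 500 than at gain 400, with a difference of -0.871 percentage points on array 1 and -0.0874 on array 2, a mean of -0.479 ± 0.554 (SD, n = 2 arrays), which is smaller than its own spread. An exact test over the sign changes of these 2 differences, chosen after the data were seen, gave a two-sided p of 0.5, the smallest it allows, and the exact permutation test that ignores the slide gave 0.667. The rule decides the level, and on array 2 the direction: counting probes above the 95th percentile of the negative control spots gave 51.7% at gain 400 and 52.4% at gain 500, with a difference of -0.783 on array 1 and 2.16 on array 2, a mean of 0.690 ± 2.08 (SD, n = 2 arrays).

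Most of the measured light came from few probes. The brightest 1% of earthworm probes, 2413 in number, held 64.8% ± 0.156 of the background-subtracted signal at gain 400 and 50.1% ± 0.143 at gain 500 (SD, n = 2 arrays). Both shares are lower limits, because saturated probes are clipped at 65535, and they are not comparable between gains, since 133 probes on average were saturated at gain 400 and 825.5 at gain 500. Among probes not saturated at gain 400, TA4-053293 had a foreground intensity of 64806 on array 1 and 64435 on array 2, and TA4-161822 had 63774 and 65053. The mean foreground intensities of the 10 brightest such probes lay between 60822.5 and 64620.5 at gain 400. All 10 were saturated at gain 500.

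The second comparison set array 2 against array 1, which had received the same RNA. Among probes detected on both, the arrays differed little. At gain 400 the median log2 ratio of array 2 over array 1 was 0.03 with an SD of 0.21 across the 52806 probes detected on both, and at gain 500 it was 0.02 with an SD of 0.21 across 51992 probes. After centring, 99.9% of ratios at gain 400 lay within 2-fold, with 30 probes outside, and 24 probes lay outside at gain 500. Without the detection filter 74.9% of ratios at gain 400 and 73.3% at gain 500 lay within 2-fold. Of the probes detected on either array, 74.8% were detected on both at gain 400 and 75.3% at gain 500. The 2 scans of one array shared detection at much the same rate, 75.2% on array 1 and 75.5% on array 2.

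The spread of the ratio between arrays was largest among dim probes. From the dimmest to the brightest of 4 equal bins of probes at gain 400, the SD of the log2 ratio was 0.29, 0.23, 0.15 and 0.10. Rescans of one slide, over unsaturated probes detected on both scans, came close to this. The SD of log2 gain 500 over gain 400 was 0.27, 0.21, 0.13 and 0.07 on array 1. On array 2 it was 0.28, 0.21, 0.13 and 0.07, so the wide spread of dim probes was not particular to comparing 2 slides. Array 2 read lower for TA4-164358, by a log2 ratio of -1.69 at gain 400 and -1.41 at gain 500, and for TA4-121142 (-1.32 and -1.12). It read higher for TA4-097352 (1.55 and 1.11) and TA4-237726 (0.94 and 1.36). Across probes, which are not independent replicates, Pearson's r was 0.994 and Spearman's rho 0.985 at gain 400. Without the filter on detection the SD rose to 1.12 at gain 400 and 1.26 at gain 500, and without background subtraction it was 0.12 and 0.14. The lower SD does not show closer arrays, because a background left in both readings shrinks the log2 ratios of dim probes. At gain 400 its median was 42.5, against a median net intensity of 67.5 in the dimmest bin.

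The third comparison asked what the higher gain did to the readings of one slide. Gain 500 made the same spots 5.09 ± 0.0258 times as bright (SD, n = 2 arrays), a median log2 ratio of 2.35 on array 1 and 2.34 on array 2. The ratio was close to even over the range, from 2.32 to 2.38 in 4 equal bins of probes by brightness on each array. The background rose as well: the median of the negative control spots was 52.5 ± 0.707 at gain 400 and 177.75 ± 8.84 at gain 500, and that of the local background 42.5 ± 0.707 and 134 ± 9.90 (SD, n = 2 arrays). Saturated earthworm probes numbered 133 ± 1.41 at gain 400 and 825.5 ± 7.78 at gain 500 (SD, n = 2 arrays). The difference was 688 probes on array 1 and 697 on array 2, larger than the spread between arrays, although the exact test over sign changes cannot go below its two-sided p of 0.5 with 2 arrays. Counting probes with any saturated pixel gave 212.5 at gain 400.

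No probe passed the test between gains when all earthworm probes were fitted after quantile normalisation. In limma 0 of 241399 probes had an adjusted p below 0.05, the lowest adjusted p being 0.935, and 12713 had an unadjusted p below 0.05. The median absolute log2 difference was 0.14, and 166 probes differed by more than 2-fold without passing the test. With the array number as a block, which left 1 residual degree of freedom, 0 probes passed and 12126 had an unadjusted p below 0.05. Both counts of unadjusted p are close to what 241399 probes would give with no difference at all. The test had little power for small changes: in data simulated for this comparison over 241399 probes it recovered 0% of probes changed by 1 on the log2 scale, 30% of those changed by 2 and 98% of those changed by 4. The simulation gave probes of like brightness 1 common variance and independent noise, with no slide effect and no normalisation after the changes. Recovery in the real data may therefore differ. Median centring in place of quantile normalisation gave 37398 calls, of which 33501 were higher and 3897 lower at gain 500. These calls cannot be read as probes that responded differently to the gain. The same offset of 50 was added at both gains, which lifts dim readings more at gain 400, and centring does not undo this. Without the offset, the median log2 ratio of detected unsaturated probes was 2.32 to 2.38 in all bins by brightness. Undetected probes are not covered by these ratios. How many of the calls come from the offset was not tested, as median centring was not run without it. Among probes detected on all 4 scans 145 passed, 51 higher and 94 lower, and each of the 145 was saturated on at least 1 scan. Without background correction 142 passed, all lower at gain 500 and all saturated on at least 1 scan.

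The control spots gave the floor and the ceiling of the measurement. Agilent's E1A spike-in probes, which detect transcripts derived from an adenovirus gene that can be added during labelling, stepped through nearly the whole scale with 60 spots each. At gain 400 the mean of the array medians was 53.5 for (+)E1A_r60_3, 125.5 for (+)E1A_r60_a20, 391.75 for (+)E1A_r60_a22, 3868.75 for (+)E1A_r60_n11 and 30488 for (+)E1A_r60_1. At gain 500 these became 185.75, 551.25, 1897.75, 19599 and 65535, the last being the top of the scale, where all 60 spots of (+)E1A_r60_1 were saturated. The share of spots detected at gain 400 was 0% for (+)E1A_r60_3, 0.833% for (+)E1A_r60_a104, 6.67% for (+)E1A_r60_a107, 17.5% for (+)E1A_r60_a135, 94.2% for (+)E1A_r60_a20, and 100% for the others. The medians of 8 of the 10 E1A probes exceeded the 95th percentile of the negative control spots on all 4 scans. Among these 8 was (+)E1A_r60_a135, so failing the detection rule does not show that a probe gave no signal. The concentrations of the spike-in transcripts are not given in the sources used here.

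**Figure D1:**
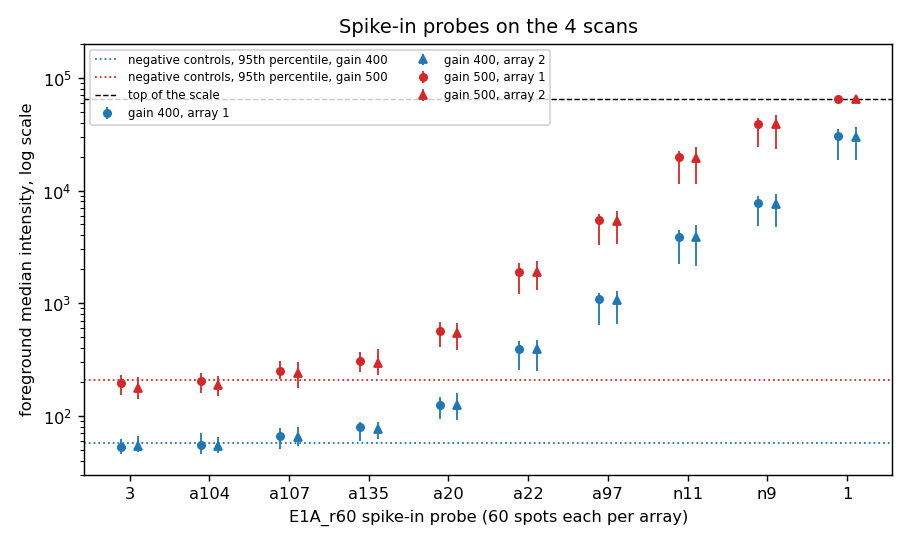
Foreground median intensity (log axis, scanner units) of the 10 E1A spike-in probes, with symbols at the median of 60 spots and bars from the lowest to the highest spot, for each array and gain. Medians at gain 500 lie above those at gain 400 for all 10 probes, with (+)E1A_r60_1 held at the top of the scale, 65535, at gain 500, and the dotted lines mark the 95th percentile of the negative control spots, as the mean of both arrays.

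The other control families differed in whether they gave signal. Of the 18 DCP probes, 15 had medians above the 95th percentile of the negative control spots on all 4 scans, and at gain 400 the mean of the array medians ran from 34540 for DCP_1_0 to 51.5 for DCP_1_11. The bright corner spots read 335.5 ± 3.54 and the dark corner spots 53.5 ± 0.707 at gain 400 (SD, n = 2 arrays). None of the 4 eQC and none of the 12 RC probes passed that mark on all 4 scans, and 1 of the 13 ETG probes did.

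Spots of one spike-in probe varied with their place on the slide, a relation examined after the data had been seen. For the 5 E1A probes detected in all spots and unsaturated at gain 400, the log2 SD among 300 spots was 0.25 on array 1 and 0.29 on array 2, whereas the same spot differed between the arrays with an SD of 0.10. In the first of 9 bands of rows the median deviation from the probe's own median was -0.39 on array 1 and -0.50 on array 2, and in the last band -0.38 and -0.39. In bands 3 to 7 it lay between 0.03 and 0.18. Earthworm probes were detected less often in the same end bands, at 23.5% on array 1 and 23.4% on array 2 against 26.6% and 27.1% in bands 3 to 7, at gain 400.

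**Figure D2:**
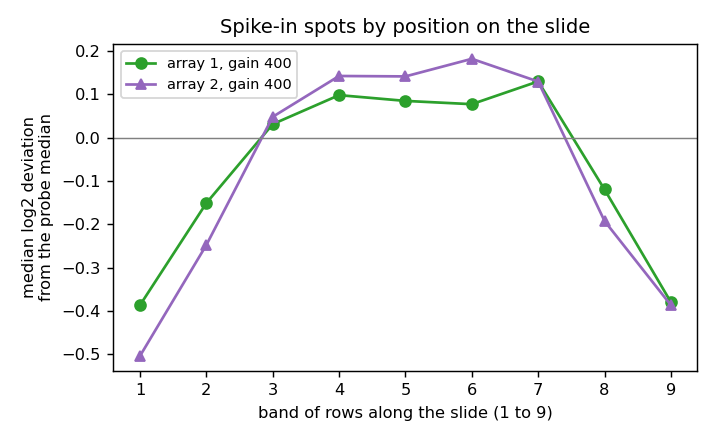
Median log2 deviation of E1A spike-in spots from the median of their own probe, by band of rows along the slide (1 to 9), for array 1 and array 2 at gain 400. Both arrays read lowest in bands 1 and 9, between -0.50 and -0.38.

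The detected share also depended on the serial number in the probe identifier, as seen after the data had been examined. The 23909 probes numbered above 217490 were detected at 7.17% ± 0.0325 at gain 400 and 6.93% ± 0.293 at gain 500, while the probes up to that number were detected at 27.6% ± 0.252 and 27.1% ± 0.838 (SD, n = 2 arrays). In windows of 2000 consecutive numbers, the 108 windows before the break ranged from 19.7% to 36.9% over the 4 scans, and the 11 windows after it from 4.6% to 10%, so that the ranges did not overlap. Smaller steps occurred before the break on all 4 scans. On array 1 at gain 400 the share fell from 34.55% to 25.25% past number 138000, and from 32.4% to 21.4% past number 150000. The break was placed where the running sum of departures of the ranked gain 400 intensities from their mean was largest. It was thus chosen from these same intensities, so a difference across it is partly built in.

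**Figure D3:**
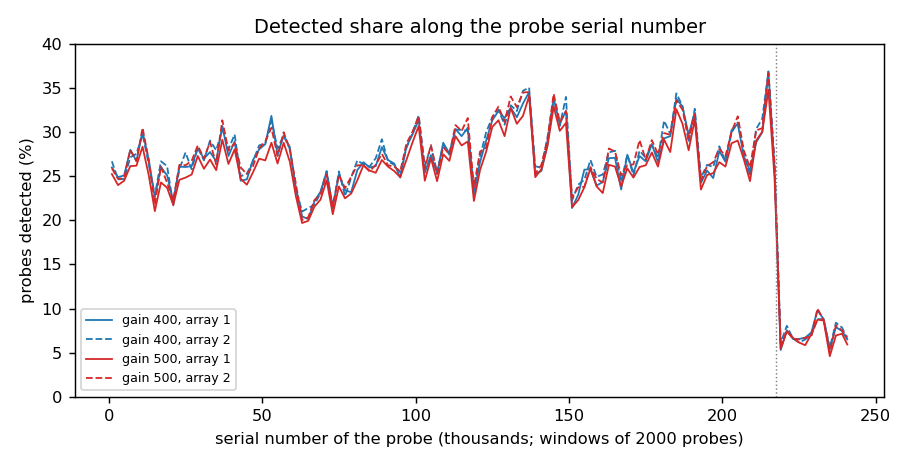
Share of earthworm probes detected (%) along the serial number of the probe identifier, in windows of 2000 probes, with 1 line for each of the 4 scans. The share falls to between 4.6% and 10% beyond number 217490, marked by the dotted line, on all 4 scans.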

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

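The ETG, eQC and RC control probes were left out of the comparisons of earthworm probes between arrays and gains. Of these controls, 1 stood above the 95th percentile of the negative control spots on all 4 scans. ETG05_36762 had a mean of array medians of 156.75 ± 3.89 at gain 400 and 682.5 ± 17.0 at gain 500, against 52.5 ± 0.707 and 177.75 ± 8.84 for the negative control spots (SD, n = 2 arrays). On average over both arrays 98.75% of its 40 spots were detected at each gain, while the 12 other ETG probes had means between 53 and 57.5 at gain 400. What this probe detects is not given in the sources used here, and no explanation was tested.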

How the results depend on the processing

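The alternatives for the difference in detected share between gains were chosen after seeing the data, and the others before; 28 values moved and 1 reversed, and the cause was not tested. The rest stayed within 1 SD between arrays, a 95% interval for agreement, or a factor of 1.5 for counts. Some could not move: spots with a bad mark kept (there were 0), the SD without centring, and agreement from the identical value table. Nor could means over 2 arrays judged by 1 SD when 1 array was left out, since their shift is always below that SD. The share detected became 20.4% and 19.99% (gains 400 and 500) at a signal-to-noise score of at least 3, and 51.7% and 52.4% above the 95th percentile of negative controls. The mean difference between gains, -0.479 points, reversed to 0.690 under the latter rule, where the arrays went opposite ways, and was -0.421 under the former and -0.871 to -0.0874 without 1 array. The SD of the log2 ratio between arrays became 0.12 and 0.14 without background correction, 0.13 and 0.17 with normexp, 0.18 and 0.18 with the foreground mean, and 1.12 and 1.26 without the detection filter (210447 and 205978 probes). Background left in, or the offset of 50 added by normexp, shrinks the log2 ratios of dim probes, so the first 2 settings do not show closer arrays. The percent within 2-fold became 99.9867 and 99.9923 without background correction, 99.9886 and 99.9942 with normexp, 99.975 at gain 500 with the foreground mean, and 74.9 and 73.3 without the filter. Probes that differed between gains in limma rose from 0 to 37398 with median centring, 142 without background correction and 145 among probes detected on all 4 scans. The array number as a replicate block gave 0, but that fit left 1 residual degree of freedom, so it cannot show that pairing makes no difference. Leaving out 1 scan gave 0 to 0, which says nothing about stability: 1 residual degree of freedom was left, and the lone scan was assumed to vary like the other gain. Saturated probes at gain 400 became 212.5 with any saturated pixel (1141.5 at gain 500, within the factor), and the log2 gain ratio 2.24 without background correction. By foreground mean the negative control read 57.5 and 206.75, and (+)E1A_r60_a22 345.75 and 1680.25. Leaving out 1 array gave 25.4% to 25.7% and 24.5% to 25.6% detected, and a log2 gain ratio of 2.34 to 2.35. Alternatives for probe length, shared targets and gene lists were not run, as the files used here give none of these. As to signal over background, 66.9% of probes were detected on no scan by the main rule of 2 background SDs, a share that depends on that rule. At gain 500 the 825.5 saturated probes have only a lower bound.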

Other observations

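The serial break, the slide sectors and the spike-in positions were examined only after the data were seen, and the tests of slide position, local background, scanner noise and random spot noise were chosen after their results were seen. No biological explanation was tested for any of them, since both arrays carried 1 RNA pool.

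The lower detection of probes numbered above 217490 may have several sources, and 2 of them are argued against. Slide position would leave the shares alike within sectors, yet the later probes were detected less often in 36 of 36 sectors on each scan, by 16.5 to 24.2 percentage points. Higher background around the later probes would raise their median local background, and its largest excess over that of the earlier probes was 0 intensity units. A single loss of brightness common to all later probes, over the same range of transcripts as the earlier ones, stayed open. Earlier over later net intensity was 8.99-fold at the 95th percentile and 16.3-fold at the highest percentile taken. Its log2 ranged by 0.85 over 5 percentiles (bootstrap 95% interval 0.58 to 1.26). The whole interval lay above the 0.5 that a common loss allowed, but it spanned the 1 set to exclude it. Whether the later probes cover the same range of transcripts is not known, so these percentiles cannot decide. Length, strand and target of the later probes were not tested, as the files used here do not give them.

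The log2 ratio of array 2 over array 1 varied across the slide, with sector medians from -0.13 to 0.13 at gain 400 and from -0.14 to 0.10 at gain 500. Scanner noise of single scans is an unlikely source, since the 36 sector medians at the 2 gains correlated at Pearson's r = 0.94 and Spearman's rho = 0.90 (permutation p = 1e-05 for each, adjusted p = 1e-05, r = 0.90 without the 2 farthest sectors). Different probes in different sectors are also argued against: spike-in spots, the same sequences throughout, gave sector medians that correlated with those of earthworm probes at r = 0.86 and rho = 0.81 (permutation p = 1e-05 for each, adjusted p = 1e-05, r = 0.81 without the 2 farthest). Each family held 2 relations, 1e-05 is the smallest p that 100000 permutations can give, and neighbouring sectors are not independent, so these p-values are too small. A difference in hybridisation or washing between the slides stays open and was not tested.

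Spots of one spike-in probe differed more within an array than the same spot did between arrays. On array 1, where this was run, a spot's deviation from its probe's median correlated with the mean of its 10 nearest spots of other spike-in probes at r = 0.96 and rho = 0.90 over 300 spots (permutation p = 1e-05 for each, adjusted p = 1e-05, r = 0.96 without the 2 farthest). Independent noise of single spots would leave no such correlation and is argued against. A smooth change of signal across the slide predicts such a correlation and may account for the spread there. Its prediction was met by the same value, so this is not a second, separate test. Neighbouring spots are not independent, which makes these p-values too small. Negative control spots hardly fell in the end bands, with gain 500 medians in bands 1 and 9 of 181 and 183 on array 1 (183.5 to 191 in bands 3 to 7) and 164 and 175 on array 2 (169.5 to 176), which goes against a scanner that dims all light there, but how much of that reading is light is not given in the sources used here, so scanner and hybridisation both stay open.

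On array 1, 2 control spots stood apart from the other spots of their probes. At gain 400 a single spot of ETG09_48764 read 432, the next brightest of its 40 spots 61, and the same spot on array 2 read 51. A single spot of ETG09_35454 read 201, the next brightest 63, and the same spot on array 2 read 49. At gain 500 these 2 spots read 1974 and 1235 on array 1, and 200 and 162 on array 2. None of the 40 spots of ETG09_48764 on array 1 passed the detection rule at gain 500, including the spot that read 1974. At gain 400 on array 1 their pixel mean was 2.06 and 1.67 times their median, a ratio above 99.98% and 99.96% of earthworm probes within 2-fold of their brightness. Both spots had first been chosen as the third pattern to weigh and were replaced by the spike-in positions after these values were seen, so no explanation is drawn for them. The spot of ETG09_35454 lies in row 672 at column 217, and TA4-164358, which read 201 on array 1 and 100 on array 2, lies in the same row at column 219. For probes detected on all 4 scans the log2 SD between arrays was 0.19 at gain 400 and 0.20 at gain 500, against 0.18 and 0.17 between the 2 scans of array 1 and of array 2 without saturated probes.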
